A study of Homo sapiens with 6 samples.

How the data were processed

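RNA sequencing of THP-1 cells, an established human monocytic acute myeloid leukemia line that carries the KMT2A-MLLT3 fusion, was analysed in 6 libraries. Per the labels, 2 libraries came from cells with a non-targeting control hairpin (NTC), 2 from cells with hairpin shLIMK1_1 and 2 from cells with hairpin shLIMK1_2, each pair numbered as biological replicates 1 and 2. Per the labels, cells were selected in puromycin for 72 h after lentiviral transduction, kept in medium with 10% serum and 0.0025% DMSO from day 4, and lysed for RNA on day 8; libraries were made with a strand-specific kit. The labels do not say whether replicates 1 and 2 were separate transductions, so every p-value below measures the spread between these libraries and nothing wider. Hairpin sequences are not used here.

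Per the submitters' processing notes, the authors used bcl2fastq 2.19.0.316, STAR 2.5.2b, SAMtools 0.1.19 and Subread 1.5.1 (featureCounts) with the human genome build hg19/GRCh37. The deposited tables hold, per the file headers, read counts per gene on each strand setting and without regard to strand for 57820 genes, with no scaling. They also hold, per the file headers, TPM values, which the authors made from the same counts by dividing by gene length and scaling each library to a common sum. The reverse-stranded counts are the sense counts of this kit and were used for every main test. The counts on the opposite strand made up 5.11% to 5.25% of both stranded totals together. The sense totals ran from 37877038 to 45596194 counts per library. How reads shared between near-identical genes were counted is not given in the sources used here. The counts of AKR1C2 (beside AKR1C1 and AKR1C3), IFITM1, COX7C, ARPC3, the HLA class II genes, the tubulins and the histone genes are therefore uncertain where copies share sequence. Gene types came from GENCODE release 29 by gene identifier, which matched 52338 of the 57820 genes and gave 19263 protein-coding genes.

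Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15903 genes. Libraries were scaled by TMM, and a robust quasi-likelihood model with 3 groups was fitted to all 6 libraries with 3 residual degrees of freedom. Quasi-likelihood F-tests compared shLIMK1_1 with NTC, shLIMK1_2 with NTC, the mean of both hairpins with NTC, and shLIMK1_2 with shLIMK1_1. Every adjusted p for a gene is from these edgeR tests with Benjamini-Hochberg adjustment over all genes tested, and the threshold was 0.05. Standard errors (SE) are the size of the log2 fold change divided by the square root of F. CPM values (counts scaled to a common library size by TMM) are given per library or as mean and SD with n = 2 per group. These tests, the groups, the gene lists and the rule for named genes were fixed before the data were examined.

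The replicate numbers were then checked for pairing, before the calls of the fits were compared. The deviations of log2 CPM from the group means correlated between replicates of the same number at 0.32 (NTC with shLIMK1_1), 0.28 (NTC with shLIMK1_2) and 0.49 (shLIMK1_1 with shLIMK1_2). Of the 4 possible ways to number the replicates, 1, that of the labels, put every correlation over 0.1. Where 1 strong difference runs within every group, 1 of the 4 numberings does so in any case. Labels that pair nothing would then match it in 1 of 4 cases. The numbers were taken to pair the libraries, and all values with the replicate block rest on that assumption. This pairing comes from the data alone, since the labels do not say what a replicate number marks. Values from the edgeR fit with the replicate number as a block (2 residual degrees of freedom) are called values with the replicate block, and stand beside the counts of genes and beside many of the genes and lists whose call or count they change. The common biological coefficient of variation was 0.201 without and 0.120 with the replicate block.

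Gene lists (29 lists, 760 names) were written from general knowledge, apart from the S phase and G2/M lists, which ship with a single-cell toolkit. Of the names, 1 was not found in the tables. Lists with at least 5 tested members (28 lists) were tested by camera on the edgeR fit with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera was run again with an estimated correlation, and fry was run as a directional test. For each list, members past the threshold were counted among all genes tested and again adjusted over the list alone. Camera compares a list with the other genes, so a list can pass it with no member past the threshold.

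The rule for named genes took LIMK1, LIMK2, CFL1, CFL2, HOXA9, MEIS1, CDK6, MYC, CD14, ITGAM and CDKN1A in every case. For the mean of both hairpins it took up to 10 genes in each direction by size of change, past the threshold with each hairpin, with a mean of at least 5 CPM and with all 4 knockdown libraries on the same side of both NTC libraries. For each other comparison it took up to 6 genes in each direction, past the threshold, at the same level. Candidates were protein-coding genes. From each list it took up to 4 members with the smallest adjusted p for the mean of both hairpins. Parts with fewer than 3 such genes were filled up to 3 with the genes of smallest p, given here as not past the threshold. The same rule was later applied to the calls with the replicate block, a choice made after seeing the data. The genes IL1B, SLC7A11, DUSP4, BIN1, FCER2, BTG2, VAT1L and HMOX1 with shLIMK1_1 were named after their values were seen. So were BTG2, C1QA, OAS3, HERC6, SAMD9L, TUBA4A, SLC2A3, PAQR8, CEBPE and LPL with shLIMK1_2, and the list members named for the difference between the hairpins. Of the genes that passed, 1 is not reported here: it stays in the counts of genes and is left out of the named genes and the plots of single genes.

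Both hairpins were compared with the same 2 NTC libraries, so their fold changes share chance values. To give the size of this, counts of unchanged hairpins were simulated 25 times against simulated controls, and the same fit was run on them. The controls could not be split, since each part would hold 1 library. The expected overlap of independent call lists was also computed, from the number of calls in each direction. The tests were also run on simulated data with 200 changed genes per set, with each fit run on data drawn from that fit. The values with and without the replicate block thus come from different data and do not measure its gain in these libraries. Without the replicate block, 23.2% of genes changed 2-fold and 84.5% of genes changed 4-fold were called for shLIMK1_1, against 71.7% and 93.9% with it. False calls made up 2.29% to 6.25% of calls over these simulated settings.

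Alternatives fixed in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom and limma on log2(TPM + 1) (limma 3.58.1), no filter, at least 10 CPM in 2 libraries, protein-coding genes alone, edgeR without robust estimation, an adjusted p under 0.01, a minimum fold change of 1.5 (glmTreat), the replicate block, the 4 libraries compared alone, the 4 knockdown libraries as 1 group, and each library left out in turn. Counts without regard to strand and a correction of each library for exonic gene length (loess, span 0.3) were added after seeing the data, alone and with the replicate block. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Intervals of list medians are 95% bootstrap intervals over members from 10000 draws, and genes of a list are not independent replicates.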

Results

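RNA was sequenced from THP-1 cells, a monocytic leukemia line, that carried a non-targeting control hairpin (NTC) or either of 2 hairpins against LIM kinase 1, called shLIMK1_1 and shLIMK1_2. Each of the 3 groups had 2 libraries. The sense counts came to 43714356 and 45596194 for NTC replicates 1 and 2, 42933993 and 43740400 for shLIMK1_1, and 37877038 and 39798731 for shLIMK1_2. Of the genes counted, 15903 were tested.

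Within every group replicate 2 stood apart from replicate 1. Mitochondrially encoded genes took 2.79% and 1.42% of the counts of NTC replicates 1 and 2, 1.79% and 0.904% with shLIMK1_1, and 2.24% and 1.16% with shLIMK1_2. The 79 genes of cytoplasmic ribosomal proteins took 5.76% and 8.14% in NTC, 6.87% and 10.96% with shLIMK1_1, and 6.69% and 10.97% with shLIMK1_2. Across protein-coding genes, the deviation of log2 CPM from the mean of all libraries correlated with exonic length at a Spearman coefficient of 0.36 and −0.14 in NTC, 0.18 and −0.28 with shLIMK1_1, and 0.19 and −0.27 with shLIMK1_2. Genes with a short exonic length were thus relatively higher in replicate 2 of each group, and higher with each hairpin than in the NTC library of the same number. In a principal component analysis of log2 CPM, component 1 (35.2% of the variance) placed replicate 2 above replicate 1 in each group, although NTC replicate 2 (−12.2) lay below shLIMK1_2 replicate 1 (−11.0). Component 2 (34.0%) separated the hairpins.

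**Figure D1:**
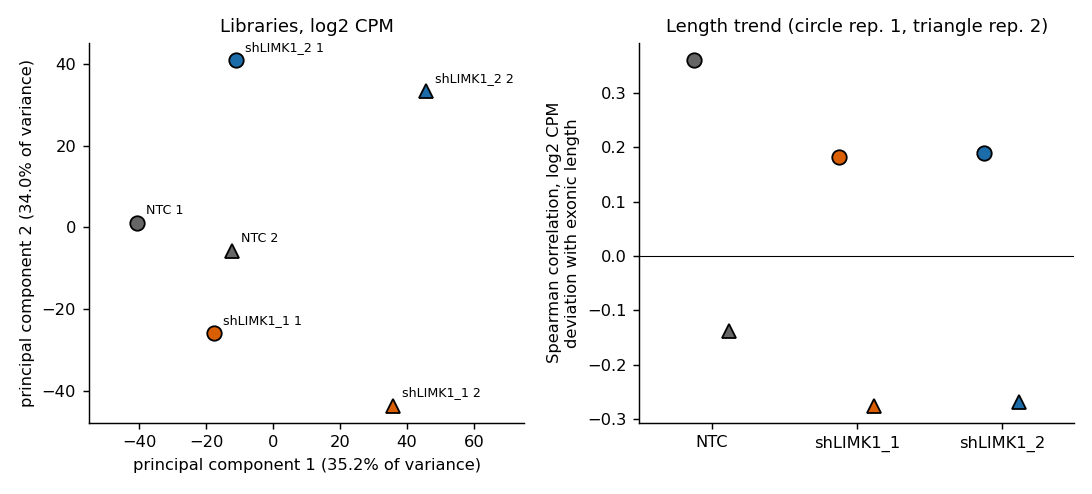
Left, principal components 1 and 2 of log2 CPM for the 6 libraries; right, Spearman correlation of each library's log2 CPM deviation with exonic gene length. Replicate 1 libraries have positive correlations with length (0.18 to 0.36) and replicate 2 libraries negative ones (−0.28 to −0.14) in all 3 groups.

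LIMK1 (ENSG00000106683.10, GRCh37 chromosome 7, 73497263 to 73536855, plus strand), which encodes the kinase that phosphorylates the actin-severing protein cofilin, was lower in all 4 knockdown libraries than in both NTC libraries. It stood at 54.0 and 49.1 CPM in NTC replicates 1 and 2, 17.1 and 14.2 CPM with shLIMK1_1, and 9.18 and 5.06 CPM with shLIMK1_2. The means were 51.6 ± 3.47, 15.6 ± 2.01 and 7.12 ± 2.91 CPM (SD, n = 2 each), so that 30.3% of the NTC level remained with shLIMK1_1 and 13.8% with shLIMK1_2. These values rest on 2514 and 2270 reads in NTC, 729 and 568 with shLIMK1_1, and 366 and 195 with shLIMK1_2.

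LIMK1 fell with shLIMK1_2, with a log2 fold change of −2.86 ± 0.29 (SE; adjusted p = 0.0115), and in the mean of both hairpins, with −2.29 ± 0.23 (adjusted p = 0.0299). With shLIMK1_1 the log2 fold change was −1.72 ± 0.28 and did not pass the threshold (adjusted p = 0.0677); with the replicate block it was −1.73 with an adjusted p of 7.4e-05. The difference between the hairpins, −1.13 ± 0.28, passed with the replicate block (adjusted p = 0.000749) and not without it (0.0802). Without NTC replicate 1 the adjusted p for LIMK1 with shLIMK1_2 was 0.296, and without NTC replicate 2 it was 0.464. The paralog LIMK2 stood at 13.5 ± 0.707 CPM in NTC, 11.8 ± 0.551 with shLIMK1_1 and 8.06 ± 0.669 with shLIMK1_2. Its log2 fold change with shLIMK1_2 was −0.75 ± 0.21 (adjusted p = 0.183, and 0.0152 with the replicate block), and with shLIMK1_1 −0.20 ± 0.21 (adjusted p = 0.843).

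**Figure D2:**
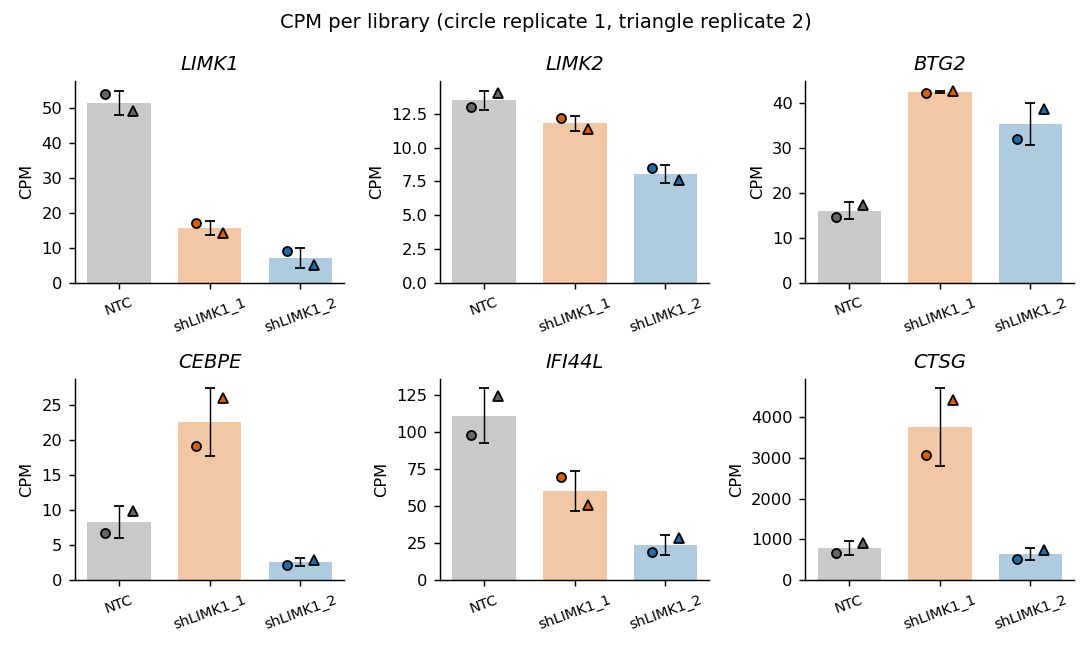
CPM of LIMK1, LIMK2, BTG2, CEBPE, IFI44L and CTSG in the 3 groups; bars are means of 2 libraries, error bars are SD, circles are replicate 1 and triangles replicate 2. LIMK1 lies between 5.06 and 17.1 CPM in the 4 knockdown libraries and at 49.1 and 54.0 CPM in NTC.

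The comparison of shLIMK1_1 with NTC asks what changes with hairpin 1. The genes that rose include those of a granule protease, several metabolic enzymes, a cystine transporter and an inflammatory cytokine. CTSG (ENSG00000100448.3, chromosome 14, 25042728 to 25045466), which encodes the neutrophil granule protease cathepsin G, stood at 787 ± 165 CPM in NTC and 3749 ± 950 CPM with shLIMK1_1 (SD, n = 2), a log2 fold change of 2.25 ± 0.31 (SE; adjusted p = 0.0346). AKR1C2 (ENSG00000151632.12, chromosome 10, 5029967 to 5060223), an aldo-keto reductase whose reads may be split with AKR1C1 and AKR1C3, rose from 2.69 ± 0.15 to 14.8 ± 5.37 CPM, by 2.46 ± 0.31 (0.0340). OSGIN1, an oxidative stress response gene, rose by 2.13 ± 0.24 (0.0340), CYP19A1 (aromatase) by 2.28 ± 0.32 (0.0392), HGD (homogentisate dioxygenase) by 2.08 ± 0.23 (0.0340) and CD209, a lectin receptor of dendritic cells and macrophages, by 1.79 ± 0.24 (0.0346). Among genes named after their values were seen, SLC7A11, the cystine transporter, rose by 1.64 ± 0.23 (0.0346) and IL1B, the cytokine interleukin 1 beta, by 1.75 ± 0.26 (0.0463).

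NPTX1 (ENSG00000171246.5, chromosome 17, 78440948 to 78451643), which encodes a neuronal pentraxin, fell from 19.3 ± 1.75 to 4.8 ± 1.48 CPM, a log2 fold change of −2.01 ± 0.30 (adjusted p = 0.0463). The other gene that fell was VAT1L (−2.62, adjusted p = 0.0340), named after its values were seen because its level was under 5 CPM. Of the genes that filled up this part, CERCAM had a log2 fold change of −1.33 ± 0.22 (adjusted p = 0.0677) and did not pass without the replicate block (0.000187 with it). In all, 23 genes passed the threshold with shLIMK1_1, 21 up and 2 down, and 1324 had an unadjusted p under 0.05. In each gene named here as past the threshold, both shLIMK1_1 libraries lay on the same side of both NTC libraries.

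A fit with the replicate block gave 1032 genes with shLIMK1_1, of which 397 were down. Among those that were up was CDKN1A, the p53-induced cell cycle inhibitor, with a log2 fold change of 0.93 ± 0.25 (adjusted p = 0.27 without and 0.000679 with the block). The count was 0 without NTC replicate 1 (edgeR, 519 genes at an unadjusted p under 0.05) and 0 without NTC replicate 2 (973). It was 385 and 86 without shLIMK1_1 replicates 1 and 2, and 325 and 329 without shLIMK1_2 replicates 1 and 2. DESeq2 called 194 genes.

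Among the lists, lysosome and neutrophil granule genes rose with shLIMK1_1 with the highest medians. Of 27 tested lysosome genes the median log2 fold change was 0.55 (camera adjusted p = 3.13e-12); none passed among all genes in edgeR, 9 were up adjusted over the list alone, and 14 were up with the replicate block. SQSTM1, an autophagy receptor, had a log2 fold change of 0.98 (adjusted p = 0.126, and 0.000318 with the block), NPC2, a cholesterol carrier of the lysosome, 0.87 (0.360 and 0.00194), and CTSA, a lysosomal carboxypeptidase, 0.86 (0.194 and 0.00115). Of 10 neutrophil granule genes the median was 0.70 (5.84e-10), CTSG passed, 7 were up adjusted over the list alone, and 7 were up with the replicate block. For both lists the adjusted p = 0.312 with an estimated correlation.

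The lists of NF-kappaB targets and inflammatory cytokines (median 0.20 over 24 genes, camera adjusted p = 0.000574), ER chaperones (0.32 over 19, 0.000574), monocyte and macrophage genes (0.23 over 34, 0.00104), the actin cytoskeleton (0.22 over 56, 0.00138), SRF/MRTF targets (0.27 over 26, 0.00284) and the nuclear-encoded respiratory chain (0.18 over 36, 0.0200) also rose. For these 6 lists the adjusted p ran from 0.403 to 0.761 with an estimated correlation. IL1B was the member past the threshold among all genes; adjusted over the list alone, 4 NF-kappaB genes, 4 SRF/MRTF targets and 5 monocyte genes were up, 1 monocyte gene and 1 actin gene were down, and 0 of the ER chaperones and respiratory chain genes passed (edgeR; with the replicate block 6 of each were up and 1 ER chaperone was down). With the block 4 NF-kappaB genes, 4 SRF/MRTF targets, 6 monocyte genes and 10 actin genes were up, and 2 monocyte genes and 1 actin gene were down. The respiratory chain genes moved with the length trend and the lower mitochondrial share of the shLIMK1_1 libraries given above, and the actin and monocyte lists were, like them, higher in replicate 2 than in replicate 1 (camera adjusted p = 0.00407 and 0.00170; adjusted p = 0.472 and 0.525 with an estimated correlation).

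The lists that fell with shLIMK1_1 were epithelial and stromal markers (median −1.01 over 5 genes, camera adjusted p = 0.000676), mitochondrially encoded genes (−0.57 over 13, 0.000963), MYC and ribosome biogenesis (−0.25 over 31, 0.00138), S phase genes (−0.12 over 43, 0.00841) and G2/M genes (−0.08 over 53, 0.0339). The adjusted p was 0.312, 0.642, 0.529, 0.642 and 0.642 with an estimated correlation. No member passed among all genes in edgeR; with the replicate block 1, 11, 4, 4 and 3 members were down. Adjusted over the list alone 2 epithelial and stromal markers were down and 0 members of the other 4 lists. In all 13 of 28 lists passed, 8 up and 5 down. Interferon-stimulated genes did not pass with shLIMK1_1 (median −0.03 over 39 genes, camera adjusted p = 0.388).

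The comparison of shLIMK1_2 with NTC asks the same of hairpin 2. Interferon-stimulated genes fell together. IFI44L (ENSG00000137959.11, chromosome 1, 79085607 to 79111830) stood at 111 ± 18.5 CPM in NTC and 23.8 ± 6.82 CPM with shLIMK1_2 (SD, n = 2), a log2 fold change of −2.22 ± 0.27 (SE; adjusted p = 0.0204). IFITM1, which encodes an antiviral membrane protein with near-identical family members, also fell (−2.32 ± 0.37, 0.0331). So did OAS3, a sensor of double-stranded RNA (−2.04 ± 0.31, 0.0295), HERC6 (−1.60 ± 0.20, 0.0204) and SAMD9L (−1.47 ± 0.20, 0.0212), named after their values were seen. Of the 39 listed interferon-stimulated genes 13 fell among all genes tested, 38 were down adjusted over the list alone, and 37 with the replicate block. Their median log2 fold change was −1.34 (camera adjusted p = 7.5e-60; adjusted p = 0.492 with an estimated correlation).

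SYTL1 (ENSG00000142765.13, chromosome 1, 27668513 to 27680421), a vesicle trafficking gene, fell (−2.54 ± 0.23, adjusted p = 0.0103). The chemokine gene CCL22 went from 13.4 ± 4.65 to 2.47 ± 0.228 CPM (−2.43 ± 0.29, 0.0204), and PRAM1, an adaptor of myeloid cells, from 24.5 ± 2.15 to 4.91 ± 0.295 CPM (−2.32 ± 0.24, 0.0115). Named after their values were seen, PAQR8 (−1.68 ± 0.20, 0.0204), the glucose transporter gene SLC2A3 (−1.83 ± 0.27, 0.0257), the tubulin gene TUBA4A (−1.55 ± 0.20, 0.0212) and CEBPE, a transcription factor of granulocyte maturation (−1.68 ± 0.29, 0.0428), fell. DLL1 (ENSG00000198719.7, chromosome 6, 170591294 to 170599561), a Notch ligand, rose from 4.1 ± 0.63 to 14.3 ± 1.51 CPM, by 1.81 ± 0.27 (0.0268). DTX4, a regulator of Notch signalling, rose by 1.79 ± 0.28 (0.0295), MYBPH, a myosin-binding protein gene, from 116 ± 12.1 to 342 ± 19.9 CPM, by 1.56 ± 0.20 (0.0206), the growth factor gene PDGFA by 1.53 ± 0.21 (0.0257), TULP3 by 1.47 ± 0.25 (0.0400) and CD180, a Toll-like receptor homolog of B cells and macrophages, by 1.36 ± 0.24 (0.0428). C1QA, a complement gene named after its values were seen, had the log2 fold change 3.76 ± 0.59 (0.0325) at a low level, 0.248 ± 0.139 CPM in NTC and 3.41 ± 2.05 CPM with shLIMK1_2.

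With shLIMK1_2, 91 genes passed, 15 up and 76 down, and 1794 had an unadjusted p under 0.05; with the replicate block 1485 passed, 610 up and 875 down. In each gene named here as past the threshold, both shLIMK1_2 libraries lay on the same side of both NTC libraries. The count was 0 without NTC replicate 1 (edgeR, 813 genes at an unadjusted p under 0.05) and 0 without NTC replicate 2 (1261), 595 without either shLIMK1_1 library, and 653 and 198 without shLIMK1_2 replicates 1 and 2. DESeq2 called 419 genes.

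Of the 28 lists, 5 passed with shLIMK1_2. Beside the interferon-stimulated genes, neutrophil granule genes (median −0.67 over 10 genes, camera adjusted p = 0.000198), cholesterol synthesis (−0.23 over 24, 0.00534) and epithelial and stromal markers (−0.78 over 5, 0.00810) fell, and the respiratory chain rose (0.28 over 36, 0.00456). The adjusted p was 0.492, 0.982, 0.492 and 0.982 with an estimated correlation. No member of these 4 lists passed among all genes in edgeR; 6 granule genes and 1 epithelial or stromal marker were down adjusted over the list alone, and 0 genes of the other 2 lists. With the replicate block 6 granule genes, 6 cholesterol synthesis genes and 1 epithelial or stromal marker were down, 10 respiratory chain genes were up, and 1 granule gene was up and 1 respiratory chain gene down. Mitochondrially encoded genes (median −0.38) passed with the replicate block (camera adjusted p = 0.000163, 6 members down; adjusted p = 0.401 with an estimated correlation) and not without it (0.229). Respiratory chain genes again moved with the length trend and the mitochondrial share of the libraries. Mitochondrially encoded genes moved with the length trend too, and that share is counted from them.

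The direct comparison of shLIMK1_2 with shLIMK1_1 tests the difference between the hairpins and uses no NTC library in its contrast. DLL1 and DTX4 were higher with shLIMK1_2 by log2 differences of 3.11 ± 0.29 (adjusted p = 0.00278) and 2.53 ± 0.29 (0.00397). So were ONECUT2, a homeobox gene, by 2.06 ± 0.31 (0.0128), CERCAM by 1.85 ± 0.22 (0.00441), the axon guidance receptor gene ROBO1 by 1.65 ± 0.25 (0.0147) and AKT1S1, an inhibitor of mTOR complex 1, by 1.32 ± 0.22 (0.0210). CEBPE (ENSG00000092067.5, chromosome 14, 23586513 to 23588825) stood at 8.3 ± 2.25 CPM in NTC, 22.5 ± 4.8 with shLIMK1_1 and 2.6 ± 0.515 with shLIMK1_2 (SD, n = 2), a log2 difference of −3.12 ± 0.30 (0.00280). CYP19A1 (−3.09 ± 0.34, 0.00392), TMEM45A (−3.02 ± 0.26, 0.00201), CCL22 (−2.90 ± 0.29, 0.00302) and MTMR7 (−2.75 ± 0.30, 0.00392) were also lower with shLIMK1_2.

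In all, 315 genes differed between the hairpins, 62 higher and 253 lower with shLIMK1_2, and 2098 had an unadjusted p under 0.05; with the replicate block 1725 genes differed, 574 higher and 1151 lower. In each gene named here, both libraries of 1 hairpin lay apart from both of the other. The count was 0 without NTC replicate 1 (edgeR, 1739 genes at an unadjusted p under 0.05) and 0 without NTC replicate 2 (1756), although neither enters the contrast. It was 661 and 566 without shLIMK1_1 replicates 1 and 2, and 582 and 584 without shLIMK1_2 replicates 1 and 2. Fitted to the 4 knockdown libraries alone it was 0 (edgeR, 1672 genes at an unadjusted p under 0.05), and DESeq2 on all libraries called 718.

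All 9 lists that passed between the hairpins were lower with shLIMK1_2. Interferon-stimulated genes had a median log2 difference of −1.21, with 20 of 39 genes lower among all genes, 37 adjusted over the list alone and 37 with the replicate block (camera adjusted p = 1.08e-44; adjusted p = 0.428 with an estimated correlation). Neutrophil granule genes had a median of −1.24, with 7 of 10 lower among all genes, 9 adjusted over the list alone and 9 with the replicate block (7.84e-19; adjusted p = 0.202 with an estimated correlation). Among them were CTSG (−2.56, 0.00499), MS4A3 (−2.03, 0.00533), the protease gene PRTN3 (−1.56, 0.0194) and MPO, which encodes myeloperoxidase (−1.31 ± 0.25, 0.0298). This was also the list that passed fry without the replicate block (adjusted p = 0.0263); with the block 4 lists passed fry, neutrophil granule genes (0.0409), ER chaperones (0.0409), cholesterol synthesis (0.0409) and lysosome genes (0.0473).

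Lysosome genes (median −0.48, camera adjusted p = 1.53e-06), ER chaperones (−0.42, 0.000575), cholesterol synthesis (−0.33, 0.000803), NF-kappaB and inflammatory cytokines (−0.08, 0.0231), glycolysis and hypoxia (−0.31 over 29 genes, 0.0311), monocyte and macrophage genes (−0.16, 0.0321) and lymphoid markers (−0.54 over 8 genes, 0.0321) were also lower with shLIMK1_2. For these 7 lists the adjusted p ran from 0.648 to 0.788 with an estimated correlation. Members lower among all genes were the lysosomal protease gene CTSL (−0.93, 0.0450), IL1B (−1.79, 0.0115), IL8, which encodes the chemokine CXCL8 (−2.17, 0.0160), the BCL2 family gene BCL2A1 (−2.67, 0.0194), SLC2A3 (−2.63, 0.00302), the integrin gene ITGAX (−1.24, 0.0341), GPNMB (−1.57, 0.0339) and GNLY (−3.25, 0.00940), while C1QA was higher (3.07, 0.0289). Adjusted over the list alone, 2 lysosome, 0 ER chaperone, 3 cholesterol synthesis, 4 NF-kappaB, 3 glycolysis, 5 monocyte and 2 lymphoid genes were lower, and 2 monocyte genes were higher. In the fit with the replicate block 14 lysosome, 10 ER chaperone, 8 cholesterol synthesis, 4 NF-kappaB, 9 glycolysis, 11 monocyte and 2 lymphoid genes were lower, and 3 monocyte genes were higher. Outside these lists SLC7A11 (−2.48, 0.00278), TUBA4A (−1.60, 0.00533) and the SRF/MRTF targets MYL9 (−1.60, 0.0122) and FHL2 (−1.40, 0.0293) were lower, and TPPP (2.48, 0.0302) and the MHC class II gene HLA-DRA (2.93, 0.0338) were higher. CDKN1A was lower (−0.66, adjusted p = 0.00337 with the replicate block and 0.264 without it), and CFL2 was higher (0.80, 0.0396 and 0.284), each past the threshold with the block alone. With the block 13 lists passed, the 9 above and 4 that were higher with shLIMK1_2: G2/M genes (0.15, camera adjusted p = 0.0188, and 0.0715 without the block), mitochondrially encoded genes (0.21, 0.0174 and 0.314), MYC and ribosome biogenesis (0.14, 0.0413 and 0.108) and replication-dependent histones (0.46, 0.0413 and 0.177). For these 4 lists the adjusted p was 0.588, 0.460, 0.699 and 0.569 with an estimated correlation in that fit.

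The mean of both hairpins against NTC, and the overlap of their calls, ask what the hairpins share. BTG2 (ENSG00000159388.5, chromosome 1, 203274619 to 203278730), a p53-induced antiproliferative gene, rose with both, from 16 ± 1.91 CPM in NTC to 42.4 ± 0.302 with shLIMK1_1 and 35.3 ± 4.67 with shLIMK1_2 (SD, n = 2). Its log2 fold changes were 1.40 ± 0.21 (SE; adjusted p = 0.0443) and 1.14 ± 0.21 (0.0474). The second of these did not pass in limma-voom (0.0513), without shLIMK1_2 replicate 2 (0.0527), or in counts taken without regard to strand (0.0505). With shLIMK1_1 and shLIMK1_2 alike BTG2 did not pass with at least 10 CPM in 2 libraries (0.0587 and 0.0512), without NTC replicate 1 (1.00 and 0.616) or without NTC replicate 2 (0.812 and 0.502). BTG2 was the 1 gene that passed in the same direction with each hairpin. In the mean of both hairpins LIMK1 was the 1 gene that passed (edgeR, 1408 genes at an unadjusted p under 0.05). PAQR8 (ENSG00000170915.8) had a log2 fold change of −1.38 ± 0.16 (adjusted p = 0.0637), BTG2 1.27 ± 0.19 (0.101), BIN1 1.28 (0.101), SYTL1 −1.36 (0.101; 0.000172 with the replicate block) and DUSP4 1.26 (0.103), none of them past the threshold without the block.

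With the replicate block 1110 genes passed in the mean of both hairpins, 518 up and 592 down, and 296 passed in the same direction with each hairpin, 174 up and 122 down. By the rule for named genes applied to these calls after seeing the data, the genes that rose the most were VSIG4, a complement receptor of macrophages (1.88, adjusted p with the replicate block = 0.000185), TULP3 (1.43, 0.000583), COX7C, a cytochrome oxidase subunit with processed pseudogenes (1.34, 0.000172), CD209 (1.32, 0.000888), GSTM3, a glutathione transferase (1.31, 0.000230), BIN1 (1.28, 0.000307), EGR1, an immediate early gene (1.28, 0.00247), FCER2, the low-affinity IgE receptor (1.27, 0.000655), BTG2 (1.27, 0.000185) and DUSP4, a MAP kinase phosphatase (1.26, 0.000485). Those that fell were LIMK1 (−2.29, 1.65e-06), NPTX1 (−1.62, 8.49e-05), IFI44L (−1.55, 0.000172), ID3 (−1.44, 0.000191), PAQR8 (−1.38, 5.43e-05), the calcium channel gene ITPR3 (−1.27, 0.000479), LSP1, which encodes an F-actin-binding protein of leukocytes (−1.26, 0.00108), SPNS3 (−1.21, 0.000230), UGT3A2 (−1.16, 0.00105) and ALOX5, which encodes the 5-lipoxygenase of leukotriene synthesis (−1.13, 0.00207). The log2 fold changes are those without the block.

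Part of any likeness between the hairpins comes from the NTC libraries they share. Independent lists of the sizes found with the replicate block would share 24.4 genes up and 21.8 down against the 174 and 122 seen. Such lists leave the shared controls out of account. In 25 simulations of unchanged hairpins at most 1 gene was shared, but those hairpins had means of only 0.28 and 0.2 calls. Another 46 genes were up with shLIMK1_1 and down with shLIMK1_2, and 6 the reverse, against 34.9 and 15.2 for independent lists. Across the 15903 tested genes, which are not independent replicates, the log2 fold changes of the hairpins correlated at 0.31 (Pearson; Spearman 0.38), against 0.49 in the simulations of unchanged hairpins. Their covariance was 0.0927 against 0.0705 simulated, and with the replicate block 0.0934 against 0.0418. The simulations drew each gene on its own, so they hold no shift of a whole library. The controls, with 2 libraries, could not be split, so part of the excess may come from them. The shared genes also moved with exonic length. Its median was 3037 bases for 156 protein-coding genes up with each hairpin, 6071 bases for 108 down, and 4815 bases for all tested protein-coding genes.

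Without NTC replicate 1 no gene passed in the mean of both hairpins or in the same direction with each hairpin, and without NTC replicate 2 none did either (edgeR, 455 and 977 genes at an unadjusted p under 0.05 in the mean). Without shLIMK1_1 replicates 1 and 2 the mean gave 443 and 124 genes, and without shLIMK1_2 replicates 1 and 2 it gave 459 and 119; genes in the same direction with each hairpin then numbered 71, 18, 66 and 15. These numbered 87, 62, 94 and 69 with the replicate block, and 2846 and 2136 without NTC replicates 1 and 2. DESeq2 called 166 genes in the mean and 26 with each hairpin.

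**Figure D3:**
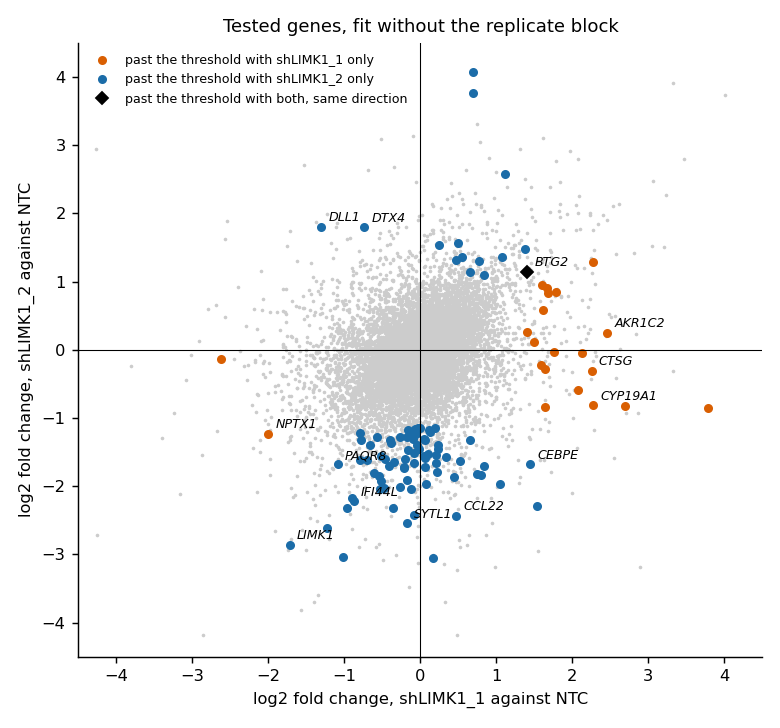
Log2 fold change against NTC with shLIMK1_1 (x axis) and with shLIMK1_2 (y axis) for the tested genes, 9 of them outside the axes; orange points passed with shLIMK1_1 alone, blue points with shLIMK1_2 alone, a black diamond in the same direction with both. The black diamond is BTG2, at 1.40 and 1.14.

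In the mean of both hairpins, 11 lists passed. Interferon-stimulated genes fell (median −0.68, camera adjusted p = 5.42e-30; adjusted p = 0.732 with an estimated correlation), with 25 of 39 down adjusted over the list alone; this mean joins −0.03 with shLIMK1_1 and −1.34 with shLIMK1_2. Lysosome genes rose (0.30, 1.05e-05; adjusted p = 0.815 with an estimated correlation), with 2 up adjusted over the list alone. Actin cytoskeleton genes rose (0.20 over 56 genes, 0.00565; adjusted p = 0.815 with an estimated correlation). In that list 10 genes were up and 1 was down with the replicate block. The actin genes included ARPC3, an Arp2/3 complex subunit with processed pseudogenes (1.18 ± 0.28, adjusted p = 0.240 without and 0.000230 with the replicate block), CAPG (0.68, 0.00240 with the block) and GSN, which encodes gelsolin (0.51, 0.00938 with the block). The respiratory chain rose (0.24, camera adjusted p = 0.00110, and 0.841 with an estimated correlation), in step with the length trend and mitochondrial share of the libraries. Mitochondrially encoded genes fell (−0.47, camera adjusted p = 0.00458, likewise 0.841), in step with the length trend. The mitochondrial share is counted from these genes, so it is no separate measure of their fall. Actin cytoskeleton genes also went with the replicate number (median log2 difference of replicate 2 from replicate 1 0.15, 17 genes higher and 4 lower).

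Epithelial and stromal markers fell (median −0.97, camera adjusted p = 7.36e-05; adjusted p = 0.554 with an estimated correlation), with 4 of 5 genes down adjusted over the list alone. The 5 tested genes, ESRP1, KRT8, FAP, PDGFRB and COL1A1, are low in these cells, at mean levels from 0.21 to 5.34 CPM. SRF/MRTF targets (0.10, 0.0333), NF-kappaB and inflammatory cytokines (0.16, 0.0380), p53 targets (0.12 over 24 genes, 0.0424) and monocyte and macrophage genes (0.16, 0.0424) rose, and MYC and ribosome biogenesis fell (−0.13, 0.0368). In this order the medians were 0.27, 0.20, 0.06, 0.23 and −0.25 with shLIMK1_1. With shLIMK1_2 they were −0.05, 0.11, 0.17, −0.07 and −0.07, and none of these 5 lists passed (camera adjusted p = 0.0772 to 0.867). The p53 targets did not pass with shLIMK1_1 either (camera adjusted p = 0.209). The monocyte and macrophage genes were also higher in replicate 2 than in replicate 1 (median 0.18, 10 genes higher and 1 lower). For the 5 lists from SRF/MRTF targets to MYC the adjusted p in the mean of both hairpins ran from 0.815 to 0.841 with an estimated correlation. No list member other than LIMK1 passed among all genes in edgeR; adjusted over the list alone 1 gene was up in the SRF/MRTF, p53, monocyte and respiratory chain lists, 1 monocyte gene was down, and 0 passed in the NF-kappaB, MYC, actin and mitochondrially encoded lists. With the replicate block 29 interferon-stimulated genes were down, 7 lysosome genes up, 9 respiratory chain genes up, 11 mitochondrially encoded genes down, 3 p53 targets up and 5 monocyte genes up, the last including LYZ, the lysozyme gene (1.05, 0.000151 with the block). With it 2 SRF/MRTF targets and 3 NF-kappaB genes were also up, and 1 NF-kappaB gene, 1 monocyte gene, 3 MYC list genes and 2 epithelial or stromal markers were down. S phase genes (−0.07) passed with the replicate block (camera adjusted p = 0.0493; adjusted p = 0.813 with an estimated correlation) and not without it (0.112). Without NTC replicate 1, 5 lists passed, and without shLIMK1_1 replicate 1, 7 lists.

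**Figure D4:**
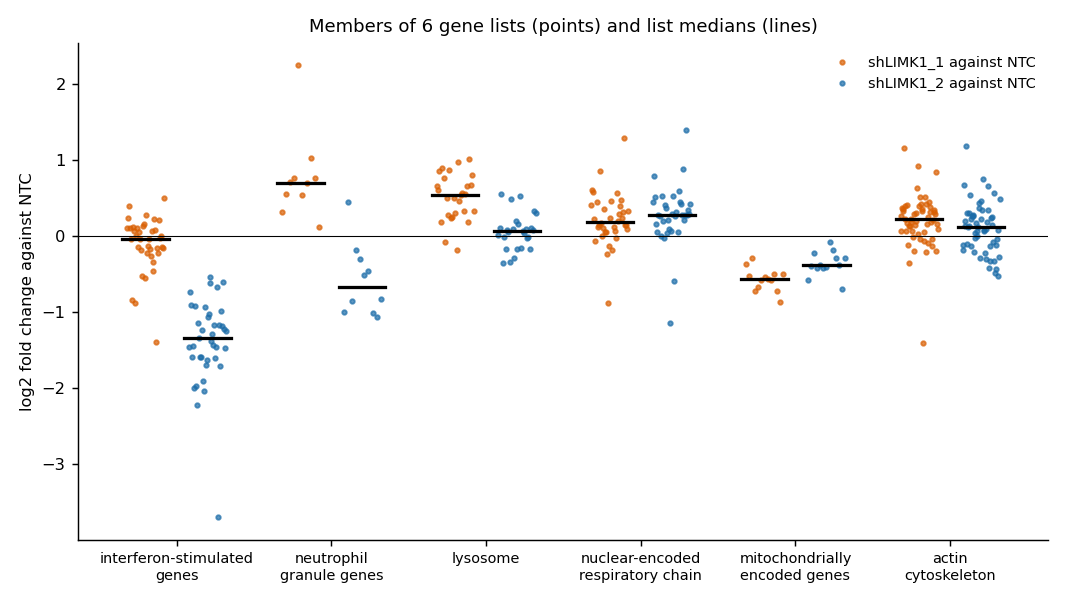
Log2 fold change against NTC of the tested members of 6 lists with each hairpin; points are genes and lines are list medians. The median of interferon-stimulated genes lies at −0.03 with shLIMK1_1 and −1.34 with shLIMK1_2, and that of neutrophil granule genes at 0.70 and −0.67.

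The remaining lists did not pass in the mean of both hairpins. The LIMK and cofilin pathway had a median of 0.09 over 23 genes (camera adjusted p = 0.904), with LIMK1 its member past the threshold. CFL1, which encodes cofilin 1, had a log2 fold change of 0.29 ± 0.20 (adjusted p = 0.742), and CFL2 0.30 ± 0.27. KMT2A fusion targets had a median of 0.01 (0.999). Their members HOXA9 (−0.09 ± 0.20), CDK6 (0.04 ± 0.21) and MEIS1 (−0.55 ± 0.56, at 0.323, 0.146 and 0.33 CPM in NTC, shLIMK1_1 and shLIMK1_2) did not pass. MYC (−0.19 ± 0.19, 0.807), CD14 (0.27 ± 0.21) and ITGAM (0.10 ± 0.17) did not pass either, and CDKN1A (0.59 ± 0.22) passed with the replicate block (0.00684) and not without it (0.484).

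The median was −0.05 (camera adjusted p = 0.862) for LSC17 stemness genes, −0.31 (0.597) for MHC class II genes, −0.05 (0.904) for the ATF4 amino acid response, 0.07 (0.204) for apoptosis regulators, −0.06 (0.628) for tubulin and microtubule regulators and 0.10 (0.230) for adhesion and migration. It was −0.08 (0.767) for small RNA machinery, 0.01 (0.971) for replication-dependent histones, 0.05 (0.767) for lymphoid markers and −0.03 over 3 tested erythroid and megakaryocyte markers, too few for camera. ER chaperones (0.11, 0.141), cholesterol synthesis (−0.09, 0.219), glycolysis and hypoxia (−0.05, 0.790), G2/M genes (−0.05, 0.429) and neutrophil granule genes (0.01, 0.451) did not pass in this mean. The median and the mean of members had opposite signs for the LIMK and cofilin, KMT2A, ATF4 and histone lists.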

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

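Of the tests below, those of a graded response to the remaining LIMK1, of an off-target effect, of chance values of the shared controls, of the replicate difference as the whole cause of shared genes and of the length trend behind the replicate axis were chosen only after the result was seen.

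The hairpins, which share a target, differed from each other in the direct edgeR test: 315 genes passed.

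Interferon-stimulated genes (median log2 difference −1.21; adjusted p = 0.428 with an estimated correlation) and neutrophil granule genes (−1.24; adjusted p = 0.202 with an estimated correlation) were lower with shLIMK1_2 than with shLIMK1_1. A response that grows as LIMK1 falls would lower both lists with shLIMK1_1 too, since LIMK1 was lower there than in NTC. For neutrophil granule genes the direction goes against this. Their median with shLIMK1_1 was 0.70 (95% bootstrap interval 0.43 to 0.90), with 0.77 within replicate 1 and 0.56 within replicate 2. The interval covers the spread of the 10 members and not that between the 2 libraries per group. This rise did not pass with an estimated correlation (camera adjusted p = 0.312) or by fry (adjusted p = 0.0629). Only its direction therefore argues against a graded response. For interferon-stimulated genes it stays open: their median with shLIMK1_1, −0.031 (−0.16 to 0.07), joins 0.22 (0.11 to 0.43) within replicate 1 and −0.26 (−0.42 to −0.15) within replicate 2, against −1.34 with shLIMK1_2. A difference between the replicate numbers that both hairpins share cancels in this comparison, since each hairpin has 1 library of each number. The difference between the hairpins was below 0 within replicate 1 (−1.51 and −1.16) and within replicate 2 (−1.02 and −1.35). The value nearest 0 was −1.02. An off-target effect of 1 hairpin may account for some of the 315 genes and stays open, since hairpin sequences are not used here.

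With the replicate block 296 genes passed in the same direction with each hairpin, which could reflect the loss of LIMK1 or something else that the knockdown libraries share. Gene-by-gene chance values of the shared controls stay open. In 25 simulations of unchanged hairpins at most 1 such gene passed. Those hairpins had means of only 0.28 and 0.2 calls, against 1032 and 1485 here, so few genes could be shared. Hairpins with separate effects against shared controls were not simulated. A chance shift of whole NTC libraries was not simulated and stays open. After the length correction with the replicate block, 215 of the 296 genes (72.6%) still passed in the same direction. This argues against a trend with exonic gene length as the whole cause. The length of the transcripts expressed in these cells was not known, so a trend with that length may remain in part. What also separates the replicate numbers was tested as the whole cause. For 58 of the 296 genes, LIMK1 among them, the mean change was above their own replicate difference, both taken in the direction of the change. A gene whose replicate difference ran the other way can count among them even where its change was the smaller. From NTC to the mean of both hairpins the libraries moved in the direction of replicate 2 by 32.6% of the replicate difference in length trend, 52.6% in mitochondrial share, 53.6% in the share of ribosomal protein genes and 85.6% on component 1, where NTC replicate 2 (−12.2) lay below shLIMK1_2 replicate 1 (−11.0). A difference that moved every gene by such a part of its own replicate difference would not account for these 58 genes. In the direction of change they moved beyond their replicate difference, by intervals widened for the selection of the genes (false coverage rate 5%). That rate lets some of the 296 intervals miss. Measures of whole libraries do not bound single genes, and component 1 was computed from the same 6 libraries. On it the mean of both hairpins lay 39.5 above the mean of NTC, whose replicates lay at −40.5 and −12.2. The test therefore speaks only of a difference that moves each gene by less than its own replicate difference. It cannot exclude, as the whole cause for the 58 genes, one that moves single genes otherwise. For 3 genes the change was below their replicate difference by its interval, as the difference alone allows. For the remaining 235 genes a knockdown effect and that difference cannot be told apart, since the intervals do not decide; 85.8% of the 296 genes had the sign of their own difference between replicates, against 67.0% of all tested genes.

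Replicate 2 stood apart from replicate 1 in every group, with correlations of the replicate deviations from 0.28 to 0.49. A trend with exonic gene length as the whole cause is argued against, since the lowest correlation was 0.25 after the length correction. A difference in the day, the passage or the handling of the cells or RNA may remain, and none of these is given in the sources used here. No biological explanation was tested, since the design gives none.

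Other lists that differed between the hairpins in the direct test, all lower with shLIMK1_2, had median log2 differences of −0.48 for lysosome genes, −0.42 for ER chaperones, −0.33 for cholesterol synthesis, −0.31 for glycolysis and hypoxia, −0.16 for monocyte and macrophage genes, −0.084 for NF-kappaB and inflammatory cytokines, and −0.54 for lymphoid markers. For these 7 lists the adjusted p ran from 0.648 to 0.788 with an estimated correlation.

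Single genes that differed in the direct test, lower with shLIMK1_2, were AKR1C2 (−2.21), CYP19A1 (−3.09), CTSG (−2.56), OSGIN1 (−2.17), HGD (−2.67), SYTL1 (−2.36), CCL22 (−2.90), PRAM1 (−1.96), IFI44L (−1.34), CEBPE (−3.12), TMEM45A (−3.02) and MTMR7 (−2.75). Higher with shLIMK1_2 were DLL1 (3.11), DTX4 (2.53), MYBPH (1.08), PDGFA (1.29), ONECUT2 (2.06), CERCAM (1.85), ROBO1 (1.65) and AKT1S1 (1.32).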

How the results depend on the processing

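Counts without regard to strand, the length correction and every setting that joins another choice to the replicate block were chosen after seeing the data. Genes past the threshold are given for shLIMK1_1, shLIMK1_2, the mean of both hairpins, the difference between the hairpins, and the same direction with each hairpin, in that order, against 23, 91, 1, 315 and 1. They were 260, 537, 252, 855 and 44 with no filter, 194, 419, 166, 718 and 26 in DESeq2, and 1032, 1485, 1110, 1725 and 296 with the replicate block. They were 0, 0, 0, 68 and 0 at an adjusted p under 0.01, and 0, 4, 0, 78 and 0 against a fold change of 1.5 (glmTreat; the 4 are SYTL1, LIMK1, PRAM1 and LPL, named after their values were seen). With at least 10 CPM in 2 libraries they were 0, 62, 0, 111 and 0. With the length correction they were 50, 196, 14, 494 and 7, and with it and the replicate block 940, 1491, 1070, 1811 and 261. The 4 libraries compared alone gave 343 and 544 for the hairpins against NTC and 0 for their difference, and the 4 knockdown libraries as 1 group gave 0. Without regard to strand, genes in the same direction with each hairpin were 0. Leaving out 1 library gave 0 to 385, 0 to 653, 0 to 459, 0 to 661 and 0 to 71, with 0 reached in each case without NTC replicate 1 and without NTC replicate 2 alone; the group left with 1 library is assumed to vary like the others. In edgeR the counts of 0 at an adjusted p under 0.01 had 1324, 1794 and 1408 genes at an unadjusted p under 0.05, those of glmTreat 497 and 351, and the other 12 counts of 0 for a comparison 455 to 1756. RLE and upper-quartile scaling, limma-voom, edgeR without robust estimation and protein-coding genes alone kept all 5 counts within 1.5 times, but the 1 gene in the same direction with each hairpin was LIMK1, lower, in limma-voom, in place of BTG2.

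With the replicate block, at least 10 CPM in 2 libraries gave 601, 979, 992 and 194 genes for shLIMK1_1, shLIMK1_2, their difference and the same direction with each. Leaving out 1 library with the replicate block gave 236 to 5214, 390 to 5177, 428 to 5062, 700 to 5592 and 62 to 2846, the highest without an NTC library. Of the 296 genes, 271 were shared in DESeq2, 283 in limma-voom, 282 without regard to strand, 190 at 10 CPM and 264 among protein-coding genes. Most of the 296 were lost whichever knockdown library was left out. Most were kept without either NTC library, in the fits that called the most genes.

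LIMK1 with shLIMK1_1 passed in DESeq2 (−1.72, adjusted p = 3.30e-06), limma-voom (−1.72, 0.0413), with no filter (−1.72), the replicate block (−1.73), the length correction (−1.68) and both together (−1.69), and ran from −1.86 to −1.58 with 1 library left out, where it passed without any of the knockdown libraries and not without NTC replicate 1 or 2. Over these settings and the other alternatives its adjusted p ran from 1.12e-08 to 1.00. LIMK1 with shLIMK1_2 did not pass an adjusted p of 0.01 (−2.86), nor 0.05 in limma on log2(TPM + 1) (−2.65, 0.0776) or without NTC replicate 1 or 2, and ran from −3.35 to −2.49 with 1 library left out. Lists past the threshold in the mean of both hairpins (11) numbered 0 with an estimated correlation, 0 by fry, and 5 to 11 with 1 library left out. The correlation of the hairpins' log2 fold changes, 0.31, was 0.37 at 10 CPM and 0.13 to 0.52 with 1 library left out.

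Over 133 results for named genes, 2349 values from the alternatives fixed in advance gave 1765 with the same direction and side of the threshold, 303 no longer past it, 276 newly past it and 5 with the sign reversed. The later alternatives gave 393 values for 131 such results, of which 329 were the same, 2 were no longer past, 62 newly past and 0 reversed. The reversed values were in the mean of both hairpins: HOXA9, −0.34 to 0.21 with 1 library left out and above 0 without NTC replicate 1; CDK6, −0.18 to 0.29, and below 0 without NTC replicate 2, shLIMK1_1 replicate 1 or shLIMK1_2 replicate 1; and SLC2A3, 0.020 with the knockdown libraries as 1 group. None of them passed the threshold. The prior degrees of freedom that stabilise each gene's spread were 6.74 on 3 residual degrees, 13.1 with the replicate block, 4.42 and 4.34 without NTC replicates 1 and 2, and 3.89 for the 4 libraries of the hairpin comparison, and were infinite with no filter and without shLIMK1_2 replicate 1. The cause of the shifts was not tested. In data simulated from each fit, 23.2% of 2-fold changes were found for shLIMK1_1 without the replicate block and 71.7% with it. As the simulated data differ between the fits, these values do not measure the gain from the block.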

Other observations

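The tests of the replicate axis by gene list and of a graded response of NRF2 targets were chosen only after the result was seen, and the list of NRF2 targets was written after the shLIMK1_1 calls were seen, with its prediction on the other members set before their values were looked at.

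Apart from the hairpins, the libraries differed by replicate number in the same direction in all 3 groups. In the edgeR fit with the replicate block 2950 genes differed between replicates 2 and 1, 1541 higher and 1409 lower in replicate 2. Of 36 nuclear-encoded respiratory chain genes 25 were higher (median log2 difference 0.54, camera adjusted p = 7.51e-19; adjusted p = 0.472 with an estimated correlation), while 12 of 13 mitochondrially encoded genes were lower (−1.0, 6.58e-34; adjusted p = 0.161 with an estimated correlation). Of 11 replication-dependent histone genes, which lack a poly(A) tail and share sequence, 5 were higher (0.72, 0.00197; adjusted p = 0.472 with an estimated correlation). Interferon-stimulated genes were higher too, 16 of 39 (0.22, 0.000296; adjusted p = 0.784 with an estimated correlation). So were monocyte and macrophage genes (0.18, 0.00170), actin cytoskeleton genes (0.15, 0.00407), cholesterol synthesis (0.23, 0.0111) and apoptosis regulators (0.18, 0.0111), while small RNA machinery (−0.30, 0.0184) and KMT2A fusion targets (−0.12, 0.0497) were lower; for these 6 lists the adjusted p ran from 0.472 to 0.525 with an estimated correlation. Within replicate 1 the median difference of interferon-stimulated genes between shLIMK1_1 and NTC was 0.22, within replicate 2 it was −0.26, and for shLIMK1_2 it was −1.28 and −1.32.

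With shLIMK1_1 the genes that rose included SLC7A11, OSGIN1, AKR1C2 and HMOX1, which are known targets of NRF2, the transcription factor of the oxidative stress response. A hypothesis is that NRF2 target genes as a group may be higher with this hairpin. Of 26 listed targets these 4 had been seen beforehand, and 21 of the other 22 were tested. AKR1C3, among the 21, also belongs to the LSC17 list, so its value may have been seen. The median log2 fold change of the 21 with shLIMK1_1 was 0.65 (95% bootstrap interval 0.45 to 0.98), with 18 above 0. Camera gave p = 3.17e-14, and p = 0.0120 with an estimated correlation. The camera p-values of these targets were not adjusted over lists, unlike those of the other lists. Without the replicate block 0 of the 21 passed in edgeR, and with it 14 were up and 2 down; the AKR1C genes among them may share reads. With shLIMK1_2 the median was −0.16 (95% bootstrap interval −0.25 to 0.08; camera p = 0.0416, and p = 0.225 with an estimated correlation), and between the hairpins it was −0.95 with 8 genes lower (p = 0.0108 with an estimated correlation). With shLIMK1_2, 0 of the 21 were up and 1 down without the replicate block, and 0 up and 4 down with it. Between the hairpins, 13 were lower and 1 higher with shLIMK1_2 in the fit with the block. These values are consistent with the hypothesis for shLIMK1_1. A response that grows as LIMK1 falls is argued against, since LIMK1 was lower still with shLIMK1_2, where the median was −0.18 within replicate 1 and −0.21 within replicate 2; an effect of that hairpin apart from LIMK1, or a response that is not graded, stays open. Whether NRF2 protein or its activity changed was not measured here.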
